A study of Homo sapiens with 12 samples.

How the data were processed

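RNA from H9 cells, an established line of human embryonic stem cells, was measured on 12 one-colour Agilent arrays, with 1 array per sample and 3 per group. The 4 groups crossed 2 kinds of cell, parental and NR5A1-transfected, with 2 media, named TF and CHIR in the labels. All groups are marked as treated with doxycycline. Per the labels' protocols, RNA was extracted with TRIzol, purified on a column kit and converted to Cy3-labelled cRNA with an Agilent low-input kit. The arrays were read out as spot intensity, and the deposited scanner files give 58717 non-control spots per array. Per the file headers, the scanner software removed a spatial background trend and a multiplicative trend to give the processed intensity of each spot, with a surrogate value for spots at background, and marked spots that were well above background, saturated or outliers. The software was Agilent Feature Extraction 10.7.1.1 per the file headers and 9.5.1.1 per the submitters' processing notes, and the conflict was not resolved. The deposited value table also holds intensity, on a linear scale. Its 12 columns share the same sorted values, so they had been quantile normalized between arrays, and the median of every column was 31.2. Its direction follows the scanner files, with a Spearman correlation of at least 0.99996 on every array. Whether any step other than quantile normalization was applied to it is not stated and stays unknown, and the values were not centred.

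The processed intensity was taken to log2, and the 75th percentile of the array's non-control spots was subtracted. Spots marked as outliers, 191 to 292 per array, were set missing, and spots of the same probe were averaged. No spot was saturated on any array. A probe was kept when it was well above background on all usable arrays, at least 2, of at least 1 group. A gene kept only through the group where it is high could only be seen to be higher there. Such genes can favour the move of a list in that direction. Of 50599 probes, 29041 passed. Each gene was represented by its probe with the highest mean over the 12 arrays, which gave 21739 genes, and 5305 genes had more than 1 passing probe. Among these, between 226 and 702 genes per comparison had probes that passed the test in opposite directions. Gene symbols came from the reference table through accessions for 28174 probes, through symbols for 2618 and through synonyms for 620, and 19187 probes kept the name in the file. The coordinates given are those of the 60-base probes as the files state them, on build hg19. No hg19 genome was at hand, so probe positions were not checked against sequence.

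Differential expression was tested with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8) for reading files. A group-means model was fitted to all 12 arrays with lmFit, and 5 contrasts were tested with eBayes: NR5A1 against parental cells under TF and under CHIR, CHIR against TF in parental and in NR5A1 cells, and their interaction. A gene passed when its Benjamini-Hochberg adjusted p over all genes of the contrast was under 0.05. Tests were two-sided. Errors are the standard errors of the model unless an SD is named. The number of arrays limits the precision. Where a gene was above background on all 3 arrays of 1 group and on no array of the other, its change is given as a lower bound, "at least N-fold". The bound sets each array of the dim group to the lowest level that any probe well above background reached on it, or to the gene's own level if that was higher. No fold is given where a gene was below background in both groups. Where some arrays of a group were above background and others not, the fold is given as measured and rests partly on background, although medians of lists with dim genes at their bound use a bound there too. An interaction is given as a bound where each dim group, raised in the same way, could only bring it nearer to 0. Those interaction bounds were added after the results were seen.

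A set of 25 gene lists was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. They covered core pluripotency, naive-associated and primed-associated genes, steroidogenesis and NR5A1 targets, cholesterol synthesis and uptake, Wnt/beta-catenin targets, primitive streak and early mesoderm, Nodal and TGF-beta targets, FGF and ERK feedback targets, definitive endoderm, later mesoderm, neuroectoderm, neural crest, trophoblast and amnion, primordial germ cell genes, HOX genes, glycolysis, oxidative phosphorylation, cell cycle, p53 and stress response, epithelial genes, mesenchymal transition, fibroblast and extracellular matrix genes, DNA methylation machinery and RNA processing controls. Between them 400 genes were tested, and 19 stood in more than 1 list. Each list was also tested with a correlation estimated from the data and with fry, which asks whether a list's own genes move, without comparing them with other genes. Negative estimates were replaced by no correlation. An estimate under the preset 0.01 makes the test less strict than the main one. A call that held with such an estimate, as where the adjusted p became smaller, is therefore no further check.

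The lists, the tests, the alternatives and the rule for the genes named were chosen before the data were examined. The rule named 12 genes whatever their values: NR5A1, POU5F1, NANOG, SOX2, KLF4, KLF17, TFCP2L1, DPPA3, TBXT, SOX17, AXIN2 and LEFTY1. For each comparison it then took the 6 largest rises and the 6 largest falls among passing genes that were above background on all 3 arrays of both groups and whose groups did not overlap, which chance gives for 10% of genes at 3 arrays against 3. It added the 4 largest lower bounds per direction and up to 4 passing members of each list. For the interaction it took the 5 largest rises and falls among genes above background on all 12 arrays. Uncharacterised names were skipped, and the text gives a selection of the genes that the rule named. Results of some genes that the rule named are not reported here.

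Alternatives changed 1 choice at a time: quantile normalization, normexp background correction with an offset of 50, the deposited value table, no filter on dim probes or only probes above background on all 12 arrays, the mean over a gene's probes, outlier spots kept, array weights, a trended robust prior, only the 2 groups compared, slide as a fixed or random block, only the slide that held all 4 groups, replicate number as a block, each array left out, an adjusted p under 0.01, and a change of at least 2-fold. The fit and the list test, but not the normalization, were also tested on simulated data with 21737 genes and independent noise. Per comparison 67 genes each were changed by 1.5-fold and 2-fold and 66 by 4-fold. These are far fewer than passed in the real data, so the shares recovered may not carry over. At a true 2-fold change the share recovered was 79.1% for NR5A1 under TF, 74.6% for CHIR in parental cells, 79.1% for CHIR in NR5A1 cells, 74.6% for NR5A1 under CHIR and 59.7% for the interaction. At a 4-fold change the shares were 93.9%, 97.0%, 92.4%, 90.9% and 89.4% in that order. No gene was called in data simulated without change.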

Results

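The 12 arrays measured gene expression in H9 human embryonic stem cells that did or did not carry introduced NR5A1, a nuclear receptor known for driving steroid-producing genes. TF is the standard medium mTeSR1. CHIR is a version of it without FGF2 and TGF-beta, to which CHIR99021, a GSK3 inhibitor that activates Wnt signalling, was added. The series concerns NR5A1 overexpression and conversion between primed and naive pluripotency. Groups are named Parental_TF, Parental_CHIR, NR5A1_TF and NR5A1_CHIR, with 3 arrays each. Median spot intensity per array was 41.5 to 53.7, the 75th percentile was 493 to 779, and 52.6% to 58.8% of spots were well above background. The labels do not say that the replicates were separate cultures, so p-values may measure only technical spread.

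Arrays of a group correlated across genes at 0.989 to 0.995. Between groups the highest correlation was 0.978, between NR5A1_TF and NR5A1_CHIR arrays, and the lowest was 0.808, between Parental_CHIR and NR5A1_CHIR arrays. The first principal component held 68.2% of the variance and the second 20.6%. The labelled passage was p15 for Parental_TF, p2 for Parental_CHIR and sp3, a notation that is not explained, for both NR5A1 groups, so passage and culture cannot be told apart in parental cells. The medium is described only for Parental_TF and NR5A1_CHIR, including the 3 µM of CHIR99021, and is taken to be the same for the other cells under the same condition. The arrays lay on 3 slides: slide 1 held Parental_TF replicates 1 and 2, slide 3 held NR5A1_CHIR replicates 2 and 3, and slide 2 held the remaining arrays, with at least 1 of every group. A fit with slide as a block and a fit to slide 2 alone therefore stand beside each count below. Slides 1 and 3 each held a single group, so the 2 fits give the same fold changes and differ only in the estimated spread. They are not separate checks, since both take Parental_TF from replicate 3 and NR5A1_CHIR from replicate 1. In the fit to slide 2 alone, the lone arrays of Parental_TF and NR5A1_CHIR are assumed to vary like the other groups.

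The comparison of NR5A1 cells with parental cells under TF asked how cells with introduced NR5A1 differ in standard medium, where the groups also differ in labelled passage, sp3 against p15, which cannot be told apart from NR5A1. Values are log2 fold changes ± SE with n = 3 per group. NLRP7, a maternal-effect gene of the oocyte, rose by 9.26 ± 0.12. DNMT3L, a cofactor of de novo DNA methylation, was at least 118.5-fold higher, FGF4, an embryonic growth factor, at least 31.0-fold, and KHDC3L, part of a maternal complex of the oocyte, at least 24.5-fold. KLF4 and TFCP2L1, transcription factors of naive pluripotency, rose by 4.55 ± 0.16 and 3.10 ± 0.20. In the other direction, ZIC5 and ZIC2, zinc-finger factors of primed cells and the neural plate, fell by 5.84 ± 0.21 and 5.55 ± 0.92. KLF4 in Parental_TF and ZIC2 in NR5A1_TF were above background on 1 of 3 arrays, so their folds rest partly on background.

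The single NR5A1 probe (A_23_P216915, chromosome 9, 127244219 to 127244278, hg19) was not well above background on any of the 12 arrays and was not tested. Known NR5A1 targets were measured. STAR, which carries cholesterol into mitochondria, rose by 3.18 ± 0.11, and NR0B1, a nuclear receptor that NR5A1 activates, rose by 3.70 ± 0.23. AMHR2, the receptor of anti-Müllerian hormone, was at least 28.3-fold higher. Of the 17 steroidogenesis and NR5A1 targets tested, 8 rose, 5 fell and 4 did not pass, and the list did not pass (adjusted p = 0.213).

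POU5F1 (A_23_P59138, chromosome 6, 31132178 to 31132237) and NANOG (A_23_P204640, chromosome 12, 7948487 to 7948546), central pluripotency factors, rose by 0.75 ± 0.06 and 1.25 ± 0.11 under TF, POU5F1 by only 0.21 with quantile normalization and 0.33 in the value table. SOX2, their partner, did not pass at 0.08 ± 0.05 (adjusted p = 0.145). KLF17, a naive-state factor, did not pass at 0.17 ± 0.09 (adjusted p = 0.123), although it passed at 0.26 with quantile normalization (adjusted p = 0.0362) and at 0.21 with array weights (0.0415). Its single probe read 4.72 in Parental_TF, near NANOG at 4.78, and was highest in Parental_CHIR, at 5.47. Whether that probe reports KLF17 was not checked, here or in the comparisons below. DPPA3, a germline and naive-state gene, was too dim to be tested. Of 24 naive-associated genes tested, 19 rose, 1 fell and 4 did not pass, with a median of 3.70, or 3.24 with dim genes at their bound. Adjusted over the list alone, 21 passed. The list moved higher (adjusted p = 8.34e-17, and 6.38e-18 with an estimated correlation). Members above background in NR5A1 cells only, such as DNMT3L, FGF4, HORMAD1 and KLF5, could only be seen to rise, which can favour this call. Of 22 primed-associated genes 17 fell, 3 rose and 2 did not pass, and 21 passed adjusted over the list alone. Examples are ZNF521, above background on 1 of 3 NR5A1_TF arrays, which fell by 5.48 ± 0.23, and DUSP6, a feedback phosphatase of ERK, which fell by 4.38 ± 0.50. That list moved lower (adjusted p = 2.45e-06, and 3.02e-07 with an estimated correlation). Of 18 core pluripotency genes 10 rose, 6 fell and 2 did not pass, and 16 passed adjusted over the list alone. UTF1 rose by 3.82 ± 0.08, GDF3 by 3.51 ± 0.10 and PRDM14 by 2.01 ± 0.10, while PODXL fell by 2.19 ± 0.13. Its call (adjusted p = 0.0435) was lost with an estimated correlation (adjusted p = 0.44) and with normexp (adjusted p = 0.065). It was also lost without Parental_TF replicate 1, 2 or 3 (adjusted p = 0.0676, 0.070 and 0.0615), Parental_CHIR replicate 1 (0.0626), NR5A1_TF replicate 1 or 2 (0.0723 and 0.0669) or NR5A1_CHIR replicate 3 (0.0547).

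Most tested members of the germ cell, endoderm and stress lists also rose. Of 13 primordial germ cell genes 8 rose, 2 fell and 3 did not pass, and 10 passed adjusted over the list alone (list adjusted p = 2.45e-06, and 5.32e-07 with an estimated correlation). TFAP2C, a factor of germ cell specification, rose by 4.52 ± 0.13, and PRDM1, which represses somatic genes in germ cell precursors, was at least 12.1-fold higher. The list shares TFAP2C and KLF4 with the naive-associated list and PRDM14 and UTF1 with core pluripotency. It shares SOX17 and PRDM1 with definitive endoderm, so its call is not separate from those lists. Its member DAZL was not higher, with a level of -3.06 in NR5A1_TF and -2.40 in Parental_TF. Of 22 p53 and stress response genes 17 rose, 2 fell and 3 did not pass, and 19 passed adjusted over the list alone. The stress cytokine GDF15 rose by 4.93 ± 0.16, the stress factor DDIT3 by 3.58 ± 0.13 and the haem oxygenase HMOX1 by 3.08 ± 0.14. The list's call (adjusted p = 4.33e-07) was lost with an estimated correlation (adjusted p = 0.0595). Of 12 definitive endoderm genes 10 rose, 1 fell and 1 did not pass, and 11 passed adjusted over the list alone. GATA6 was at least 4.47-fold higher and SOX17 at least 2.98-fold, both endoderm factors. Both were above background on no parental array and could only be seen to rise, which can favour the list's rise. This call (adjusted p = 0.0143) was lost with an estimated correlation (adjusted p = 0.243).

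Cell cycle and epithelial genes were lower in NR5A1 cells under TF. Of 22 cell cycle genes 19 fell, none rose and 3 did not pass, and 20 passed adjusted over the list alone. TOP2A, the replication topoisomerase, fell by 1.61 ± 0.10, and CDC20, an activator of anaphase, by 1.34 ± 0.07. Its call as a list (adjusted p = 0.00491) was lost with an estimated correlation (adjusted p = 0.44). Of 18 epithelial genes 13 fell, 3 rose and 2 did not pass, and 17 passed adjusted over the list alone. The keratin KRT18 fell by 3.25 ± 0.12 and the tight junction gene CLDN3 by 3.04 ± 0.17. The call for the list (adjusted p = 0.0122) was lost with an estimated correlation (adjusted p = 0.0595) and on slide 2 alone (adjusted p = 0.0562).

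No signalling list passed, although single members did. NODAL, a ligand that maintains primed cells, rose by 5.56 ± 0.42, its feedback inhibitors LEFTY2 and LEFTY1 by 4.80 ± 0.30 and 2.95 ± 0.56, and BMP4, a morphogen, by 4.93 ± 0.17. The Nodal and TGF-beta list (8 of 14 rose, 3 fell, adjusted p = 0.195) passed with slide as a block (adjusted p = 0.0171), on slide 2 alone (0.0165) and without NR5A1_CHIR replicate 1 (0.00800). AXIN2, a feedback inhibitor of Wnt signalling, rose by 2.15 ± 0.07, while the secreted Wnt inhibitor SFRP1 fell by 5.97 ± 0.15 and the Wnt receptor FZD2 by 5.48 ± 0.15. TBXT, a primitive streak factor, rose by 2.17 ± 0.78 (adjusted p = 0.0312), but it was above background on 2 of 3 NR5A1_TF arrays and 0 of 3 Parental_TF arrays, so the fold rests partly on background. It was 3.62 with slide as a block and on slide 2 alone. TBXT no longer passed with normexp (0.69, adjusted p = 0.082), without Parental_TF replicate 3 (1.44, adjusted p = 0.119) or without NR5A1_TF replicate 2 or 3 (adjusted p = 0.0861 and 0.0817). The largest lower bounds were those of IL18, an inflammatory cytokine, at least 454-fold, GSTA3, a glutathione transferase of steroid-producing tissue, at least 322.9-fold, and RGN at least 173-fold. CUZD1 was at least 318-fold lower.

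Of 21739 genes tested, 14655 (67.4%) passed, 6859 higher and 7796 lower in NR5A1 cells. At least 4-fold changes numbered 1450 higher and 835 lower. With slide as a block 13274 passed, and 12483 passed on slide 2 alone. The other 17 lists did not pass. Besides those given above, the adjusted p was 0.871 for cholesterol synthesis and uptake, 0.195 for Wnt/beta-catenin targets, for primitive streak and early mesoderm and for trophoblast and amnion, 0.219 for FGF and ERK feedback targets and 0.108 for later mesoderm. It was 0.805 for neuroectoderm and for neural crest, 0.202 for HOX genes, 0.706 for glycolysis, 0.184 for oxidative phosphorylation, 0.872 for mesenchymal transition, 0.569 for fibroblast and extracellular matrix, 0.213 for DNA methylation machinery and 0.140 for RNA processing controls. RNA processing controls, of which 12 of 18 fell, passed with quantile normalization (adjusted p = 0.0351), the value table (0.0409), slide as a block (0.0305) and without NR5A1_CHIR replicate 1 (0.0368). The later mesoderm list passed on slide 2 alone (adjusted p = 0.0165) and without Parental_TF replicate 1 (0.0391) or NR5A1_CHIR replicate 2 (0.0298).

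**Figure D1:**
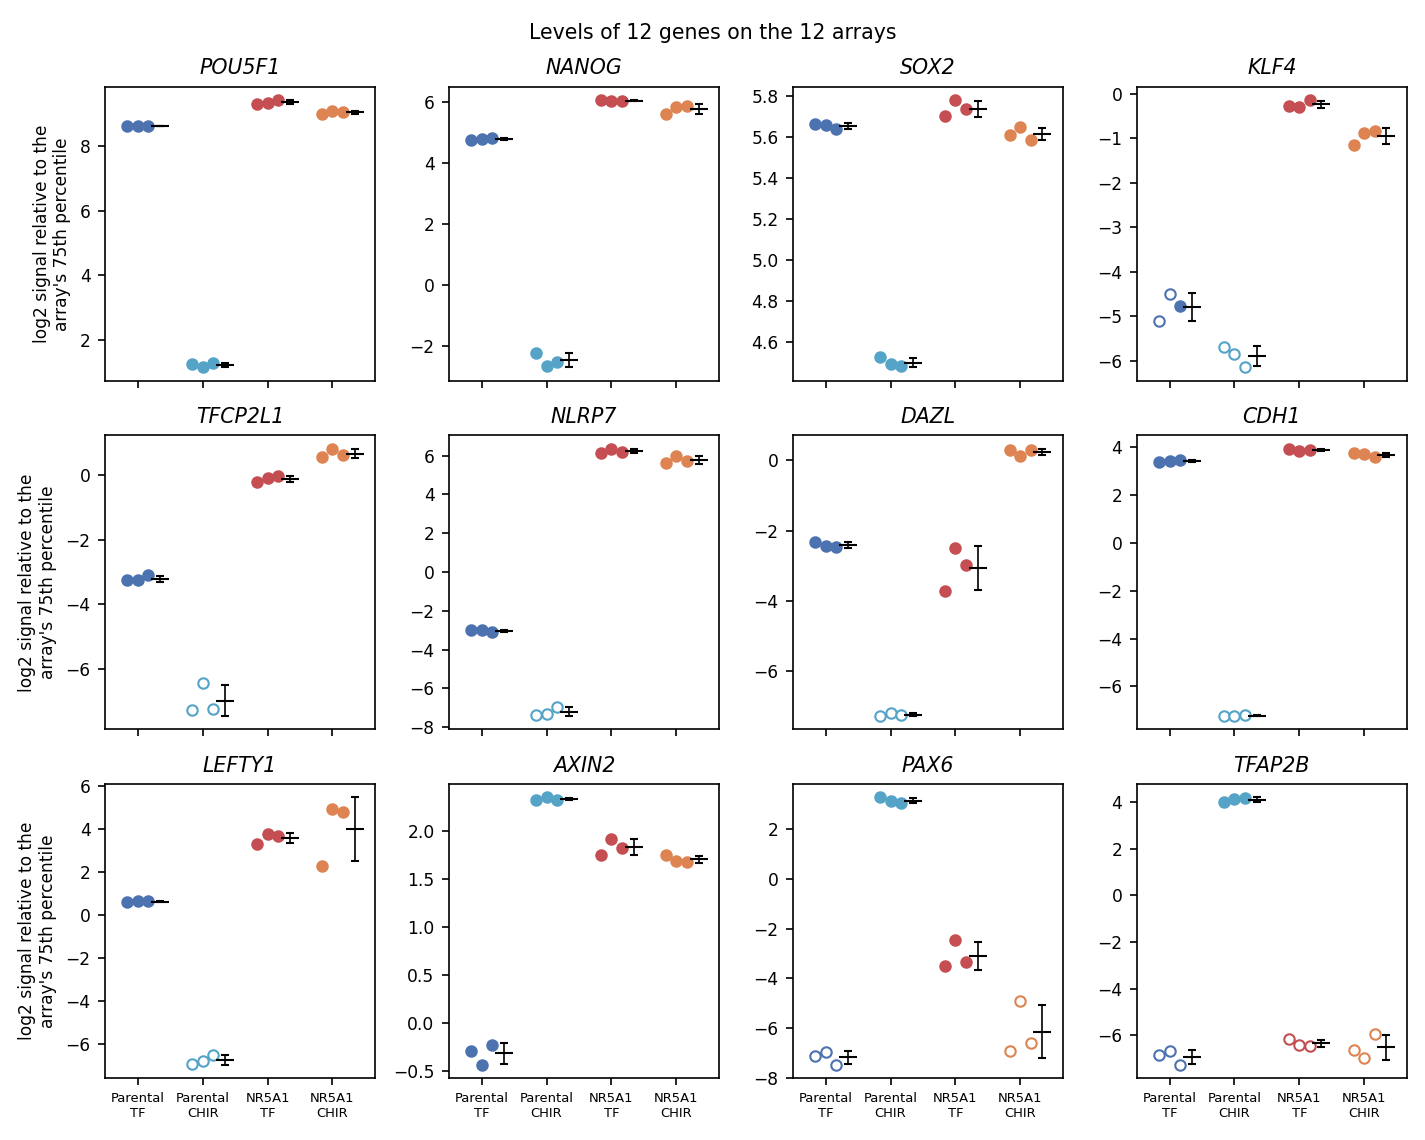
Levels of 12 genes on each of the 12 arrays, as log2 signal relative to the array's 75th percentile (y axis), by group (x axis); filled points are well above background, open points are not, and black bars give the mean ± SD of 3 arrays. POU5F1, NANOG and CDH1 lie low in Parental_CHIR alone among the 4 groups, while PAX6 and TFAP2B lie highest there.

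The comparison of CHIR with TF in parental cells asked what the CHIR medium does without NR5A1, and the groups also differ in labelled passage, 2 against 15. Most core pluripotency genes fell in parental cells under CHIR. POU5F1 fell by 7.39 ± 0.06 and NANOG by 7.24 ± 0.11 (n = 3 per group), and CRIPTO, a Nodal co-receptor above background on 1 of 3 Parental_CHIR arrays, fell by 11.01 ± 0.09. SOX2, which is also a neural factor, fell by 1.15 ± 0.05. POU5F1, NANOG and SOX2 all stayed above background on 3 of 3 Parental_CHIR arrays. CDH1, the epithelial cadherin, was at least 367-fold lower, and EPCAM, an epithelial adhesion molecule, fell by 9.24 ± 0.12. Neural and neural crest genes rose: PAX6, a neuroectoderm factor, was at least 286-fold higher, TFAP2B, a neural crest factor, at least 548-fold, and WNT1, a ligand of the dorsal midbrain, at least 731-fold. The rise of PAX6 was smaller than that bound with the mean over its probes.

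The lists moved with these genes. Of 18 core pluripotency genes 15 fell, 2 rose and 1 did not pass, and 18 passed adjusted over the list alone (list adjusted p = 3.00e-45, and 2.23e-12 with an estimated correlation). All 18 epithelial genes tested fell, also when adjusted over the list alone, including CLDN6 by 7.37 ± 0.09 (list adjusted p = 3.14e-58, and 9.30e-42 with an estimated correlation). All 15 neural crest genes tested rose, also when adjusted over the list alone. PAX3 and PAX7, dorsal neural and neural crest factors, rose by 9.86 ± 0.56 and 8.75 ± 0.39 from Parental_TF levels above background on 1 of 3 arrays, PAX7 by 5.61 with the mean over its probes, and MSX1 was at least 134-fold higher (list adjusted p = 4.67e-13, and 8.35e-07 with an estimated correlation). Of 15 neuroectoderm genes 14 rose and 1 did not pass, and 14 passed adjusted over the list alone. HES5, a Notch target of neural progenitors, rose by 7.59 ± 0.30 (list adjusted p = 3.40e-10, and 2.11e-11 with an estimated correlation). Neural and neural crest members above background in Parental_CHIR only, such as TFAP2A, DLX5, SOX1 and NEUROG2, could only be seen to rise. They can favour both calls. Of 18 mesenchymal transition genes 14 rose and 4 fell, and 18 passed adjusted over the list alone (list adjusted p = 1.68e-05, and 3.27e-06 with an estimated correlation). TWIST1 and SNAI2, factors of mesenchymal transition, rose by 6.43 ± 0.52 and 5.90 ± 0.26, also from 1 of 3 arrays above background, and ACTA2, smooth muscle actin, by 5.89 ± 0.16.

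Metabolic and growth factor genes fell. Of 21 glycolysis genes 17 fell, 3 rose and 1 did not pass, and 20 passed adjusted over the list alone (list adjusted p = 5.18e-05, and 0.0323 with an estimated correlation). The aldolase ALDOC fell by 3.42 ± 0.06 and PDK1, a kinase that inhibits pyruvate dehydrogenase, by 3.20 ± 0.09. Of 17 FGF and ERK feedback targets 15 fell and 2 rose, and 17 passed adjusted over the list alone. ETV4 was at least 31.3-fold lower and DUSP6 fell by 3.64 ± 0.50. The list's call (adjusted p = 0.000929) was lost with an estimated correlation (adjusted p = 0.189). Of 14 Nodal and TGF-beta targets 8 fell, 4 rose and 2 did not pass, and 12 passed adjusted over the list alone. LEFTY1 was at least 53.9-fold and GDF3 at least 20.5-fold lower. This call (adjusted p = 0.00539) was lost with an estimated correlation (adjusted p = 0.258) and with normexp (0.133). Of 30 oxidative phosphorylation genes 22 fell, 1 rose and 7 did not pass, and 23 passed adjusted over the list alone. SDHB, of respiratory complex II, fell by 1.11 ± 0.07. Its call as a list (adjusted p = 0.0443) was lost with an estimated correlation (adjusted p = 0.655), with quantile normalization (0.265), the value table (0.266) and on slide 2 alone (0.0718). It was also lost without Parental_TF replicate 2 or 3 (0.0525 and 0.0527), Parental_CHIR replicate 1 or 3 (0.0987 and 0.0832), NR5A1_TF replicate 1 (0.0515) or NR5A1_CHIR replicate 1 or 2 (0.0593 and 0.0612). Of 13 later mesoderm genes 10 rose and 3 fell, and 13 passed adjusted over the list alone; KDR, a receptor of vascular precursors, fell by 6.07 ± 0.10. Its call (adjusted p = 0.0375, and 0.048 with an estimated correlation) was lost with the value table (0.112), without Parental_CHIR replicate 3 (0.117) and without NR5A1_CHIR replicate 1 (0.0723).

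Wnt targets went both ways. SP5, a direct Wnt target, was at least 632.5-fold higher, LEF1, a Wnt-regulated transcription factor, rose by 7.50 ± 0.29 and AXIN2 by 2.65 ± 0.07. Of 18 Wnt/beta-catenin targets 11 rose, 6 fell and 1 did not pass (list adjusted p = 0.0816, which passed at 0.0271 with normexp and 0.0372 without NR5A1_TF replicate 2). TFCP2L1 was at least 3.74-fold lower, and KLF17 rose by 0.75 ± 0.09. KLF4 fell by 1.11 ± 0.16, a fold that rests mostly on background, since it was above background on 1 of 3 Parental_TF and 0 of 3 Parental_CHIR arrays, and it no longer passed with normexp (-0.08, adjusted p = 0.424). TBXT and SOX17 were below background on all arrays of both groups. NR2F1, an orphan nuclear receptor of neural and crest cells, rose by 10.20 ± 0.21. The long non-coding RNA ESRG, known for its expression in pluripotent cells, fell by 8.97 ± 0.18.

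Of 21739 genes 14831 (68.2%) passed, 7431 higher and 7400 lower under CHIR, and at least 4-fold changes numbered 1233 higher and 1344 lower. With slide as a block 13516 passed, and 12810 on slide 2 alone. The other 15 lists did not pass. The fibroblast and extracellular matrix list (8 of 13 rose, 5 fell, adjusted p = 0.203) passed with quantile normalization (1.81e-05), the value table (2.36e-05), slide as a block (0.0196) and slide 2 alone (0.0105), and its member LUM, a proteoglycan, was at least 123.9-fold higher. HOX genes (adjusted p = 0.0963) passed as a list with quantile normalization (0.00335), the value table (0.00423) and slide as a block (0.0482). Primordial germ cell genes (adjusted p = 0.0769) passed with quantile normalization (0.0241), the value table (0.0387) and without NR5A1_TF replicate 1, 2 or 3 (0.0226, 0.0269 and 0.0489). The p53 and stress response list (adjusted p = 0.227) passed without Parental_CHIR replicate 3 (0.0430).

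The comparison of CHIR with TF in NR5A1 cells asked whether cells with NR5A1 hold their state in the same medium change. Of 18 core pluripotency genes 4 rose, 5 fell and 9 did not pass, and the list did not pass (adjusted p = 0.693). The largest of these changes were those of ZFP42 and TERT, which both rose by 0.64, and of FGF2, which fell by 0.58. NANOG, SOX2 and AXIN2 did not pass, at -0.27 ± 0.11 (adjusted p = 0.0726), -0.12 ± 0.05 (0.0586) and -0.13 ± 0.07 (0.155) with n = 3 per group. A second AXIN2 probe (A_24_P298027), above background on all 12 arrays, was lower under CHIR. Its level was 1.33 (SD 0.17) in NR5A1_TF and 0.755 (SD 0.056) in NR5A1_CHIR, so the result for AXIN2 depends on the probe. NANOG passed in 6 alternatives, among them slide as a block (-0.45, adjusted p = 0.0412). POU5F1 fell by 0.31 ± 0.06 (adjusted p = 0.00166) but did not pass with quantile normalization (0.09, adjusted p = 0.244) or in the value table (0.01, adjusted p = 0.888). With the mean over its probes the change was -0.165 (adjusted p = 0.0452). A second POU5F1 probe (A_24_P144601), above background on all 12 arrays, read 6.83 (SD 0.052) in NR5A1_TF and 6.81 (SD 0.036) in NR5A1_CHIR. The fall of POU5F1 thus depends on the probe. Single genes known from the oocyte and germ line rose, while the primordial germ cell list did not pass (adjusted p = 0.689). OOEP, of the maternal oocyte complex and above background on 1 of 3 NR5A1_TF arrays, rose by 3.68 ± 0.39, DAZL, a germ cell RNA-binding protein, by 3.30 ± 0.24, DPPA5, a naive-state gene, by 3.13 ± 0.19, and KHDC3L by 2.67 ± 0.33. MAEL, a germ cell factor that silences transposons, was at least 4.95-fold higher.

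The histone gene H1-1 rose by 4.26 ± 0.22, the non-coding RNA LINC00458 by 3.47 ± 0.25, and DDX43, a helicase expressed in testis, by 3.60 ± 0.93. SP5 rose by 3.27 ± 0.59, and on slide 2 alone its change was 1.65 (adjusted p = 0.0618). TFCP2L1 rose by 0.78 ± 0.20, but did not pass with slide as a block (0.67, adjusted p = 0.116) or on slide 2 alone (adjusted p = 0.183). TBXT did not pass at 1.71 ± 0.78 (adjusted p = 0.101), and passed without NR5A1_CHIR replicate 1 (2.55, adjusted p = 0.0140), with array weights (2.24, adjusted p = 0.0209) and with normexp (0.86, adjusted p = 0.0466). LEFTY1 did not pass at 0.41 ± 0.56 (adjusted p = 0.579). LEFTY1 was 1.27 (adjusted p = 0.000252) without NR5A1_CHIR replicate 1, 1.08 (adjusted p = 0.0150) with array weights and -1.30 on slide 2 alone (adjusted p = 0.0112), where that replicate is the only array of its group.

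SOX17 was at least 2.91-fold lower, GATA6, above background on 1 of 3 NR5A1_CHIR arrays, fell by 2.77 ± 0.46 and BMP4 by 1.93 ± 0.17. OLIG3, a factor of the dorsal neural tube, fell by 2.90 ± 0.23 and the neural adhesion gene NRCAM by 3.28 ± 0.15. NR0B1 fell by 2.23 ± 0.23, AMHR2 by 1.94 ± 0.26 and STAR by 1.42 ± 0.11, while NR0B2, a nuclear receptor that represses NR5A family members, was at least 9.32-fold lower. Of 17 steroidogenesis and NR5A1 targets 6 fell, 4 rose, among them CYP11A1 by 0.94 ± 0.28, and 7 did not pass, and the list did not pass (adjusted p = 0.401). CYP11A1 was over 2-fold higher in NR5A1_CHIR replicate 1 than in the mean of replicates 2 and 3, so its rise rests partly on that array. PLCE1, a phospholipase, fell by 3.66 ± 0.18. KLF4 and KLF17 fell by 0.72 ± 0.16 and 0.56 ± 0.09.

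Of the 25 lists only cholesterol synthesis and uptake passed. Of its 23 genes 11 fell, 1 rose and 11 did not pass, and 14 passed adjusted over the list alone. MVD, an enzyme of the mevalonate pathway, fell by 0.84 ± 0.13 and CYP51A1, a sterol demethylase, by 0.69 ± 0.10, although MVD did not pass on slide 2 alone (-0.74, adjusted p = 0.0602). The call for the list (adjusted p = 0.0102) was lost with an estimated correlation (adjusted p = 0.601), with slide as a block (0.351), on slide 2 alone (0.453), without NR5A1_TF replicate 1 (0.0508) and without NR5A1_CHIR replicate 3 (0.0547). Definitive endoderm genes (7 of 12 fell, 1 rose, list adjusted p = 0.0846) passed as a list with slide as a block (0.0413), on slide 2 alone (0.0293), with normexp (0.0405) and without NR5A1_CHIR replicate 1 (0.0388). Without NR5A1_CHIR replicate 1, 7 lists passed, adding FGF and ERK feedback targets (0.0343), cell cycle (0.0121), glycolysis (0.0343), neuroectoderm (0.0408) and RNA processing controls (0.0388) to cholesterol and endoderm. With normexp, 8 lists passed, adding FGF and ERK feedback targets (0.0495), cell cycle (0.0258), glycolysis (0.0258), neural crest (0.0497), neuroectoderm (0.0497) and oxidative phosphorylation (0.0405). Among all genes 9711 (44.7%) passed, 5186 higher and 4525 lower, and at least 4-fold changes numbered 118 higher and 240 lower. With slide as a block 8531 passed, and 7023 on slide 2 alone. With normexp 5043 were higher and 6952 lower.

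The comparison of NR5A1 cells with parental cells under CHIR asked how the cells differ in the medium without FGF2 and TGF-beta, and the labelled passage also differs, sp3 against p2. Most core pluripotency genes were higher in NR5A1 cells. POU5F1 was higher by 7.83 ± 0.06, NANOG by 8.21 ± 0.11 and CRIPTO, above background on 1 of 3 Parental_CHIR arrays, by 11.89 ± 0.09 (n = 3 per group). NLRP7 was at least 1885.9-fold higher, DPPA5 at least 965-fold, TFCP2L1 at least 54.8-fold and KLF4 at least 17.8-fold, while KLF17 fell by 1.14 ± 0.09. SOX2 was higher by 1.11 ± 0.05, LEFTY1 at least 553.7-fold, NODAL at least 508-fold and TBXT at least 7.41-fold. NR5A1_CHIR replicate 1 was low for LEFTY1, NODAL and TBXT. Their measured changes of 10.73, 9.72 and 4.51 became 11.58, 10.29 and 5.35 without it, and 9.02, 8.58 and 2.84 on slide 2 alone, where it is the only array of its group. CDH1 was at least 445-fold and EPCAM 8.94 ± 0.12 higher. In contrast NR2F1 was at least 2293-fold lower, NR2F2, its relative, at least 851-fold, WNT1 at least 713.8-fold, PAX3 at least 515-fold, and LEF1, above background on 2 of 3 NR5A1_CHIR arrays, fell by 8.19 ± 0.29. AXIN2 fell by 0.63 ± 0.07, or 1.03 with the mean over its probes.

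The lists followed these genes. Of 18 core pluripotency genes 15 were higher and 3 lower, and 18 passed adjusted over the list alone (list adjusted p = 4.85e-34, and 1.31e-09 with an estimated correlation). Of 24 naive-associated genes 19 were higher, 2 lower and 3 did not pass, and 21 passed adjusted over the list alone (list adjusted p = 4.80e-13, and 1.05e-13 with an estimated correlation). Among 13 primordial germ cell genes 10 were higher, 2 lower and 1 did not pass, and 12 passed adjusted over the list alone. DAZL was at least 40.79-fold higher and UTF1, a chromatin factor of early embryo and germ cells, higher by 6.19 ± 0.08 (list adjusted p = 4.51e-07, and 9.45e-08 with an estimated correlation). UTF1 and other members also belong to the core pluripotency or naive-associated list. Of 18 epithelial genes 16 were higher and 2 lower, and 18 passed adjusted over the list alone. ESRP1, an epithelial splicing regulator, was at least 111-fold higher (list adjusted p = 1.05e-25, and 3.28e-18 with an estimated correlation). All 15 neural crest genes and all 15 neuroectoderm genes tested were lower, also when adjusted over each list alone. TFAP2B was at least 535-fold and PAX6 at least 273-fold lower, and HES5 fell by 7.53 ± 0.30. With the mean over its probes the fall of PAX6 was smaller than that bound. The adjusted p was 5.02e-09 for neural crest (5.82e-05 with an estimated correlation) and 1.87e-07 for neuroectoderm (2.65e-08 with an estimated correlation). Members of these lists above background in Parental_CHIR only, such as TFAP2A and SOX1, could only be seen to be lower here. Naive-associated members above background in NR5A1 cells only, such as DNMT3L, could only be seen to be higher. Of 18 mesenchymal transition genes 13 were lower, 1 higher and 4 did not pass, and 14 passed adjusted over the list alone. ZEB1, a repressor of epithelial genes, was at least 104-fold lower (list adjusted p = 9.24e-05, and 2.78e-05 with an estimated correlation).

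Stress, metabolic and signalling lists were higher in NR5A1 cells under CHIR, but each of these 5 calls was lost with an estimated correlation. Of 22 p53 and stress response genes 17 were higher, 3 lower and 2 did not pass, and 20 passed adjusted over the list alone. PMAIP1, a p53 target that promotes cell death, was higher by 7.51 ± 0.11 and GDF15 by 6.03 ± 0.16 (list adjusted p = 0.000118, and 0.144 with an estimated correlation). Of 21 glycolysis genes 14 were higher, 2 lower and 5 did not pass, and 16 passed adjusted over the list alone. ALDOC was higher by 3.83 ± 0.06 (list adjusted p = 0.000692, and 0.0800 with an estimated correlation). Of 30 oxidative phosphorylation genes 29 were higher and 1 did not pass, and 29 passed adjusted over the list alone. SDHB was higher by 1.81 ± 0.07 and NDUFV1, of complex I, by 1.44 ± 0.08 (list adjusted p = 0.000954, and 0.507 with an estimated correlation). Of 14 Nodal and TGF-beta targets 9 were higher and 5 lower, and 14 passed adjusted over the list alone. LEFTY2 was at least 301.9-fold and GDF3 at least 261.79-fold higher (list adjusted p = 0.000877, and 0.198 with an estimated correlation). Of 17 FGF and ERK feedback targets 11 were higher, 4 lower and 2 did not pass, and 15 passed adjusted over the list alone. SPRY4, an inhibitor of receptor signalling, was higher by 3.36 ± 0.19, or 1.97 with the mean over its probes. Its list's call (adjusted p = 0.0226) was lost with an estimated correlation (adjusted p = 0.436), with slide as a block (0.0618) and on slide 2 alone (0.0621).

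Of 21739 genes 17053 (78.4%) passed, 8565 higher and 8488 lower, and at least 4-fold changes numbered 2309 higher and 2139 lower. With slide as a block 15878 passed, and 15349 on slide 2 alone. The other 13 lists did not pass. Primed-associated genes (14 of 22 lower, 8 higher, list adjusted p = 0.153) passed as a list with normexp (0.0175), slide as a block (0.0205), on slide 2 alone (0.0301), and without NR5A1_TF replicate 3 (0.0459) or NR5A1_CHIR replicate 1 (0.0134). The fibroblast and extracellular matrix list (adjusted p = 0.489) passed with quantile normalization (0.00181) and the value table (0.00218). SOX17 was below background on all arrays of both groups.

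**Figure D2:**
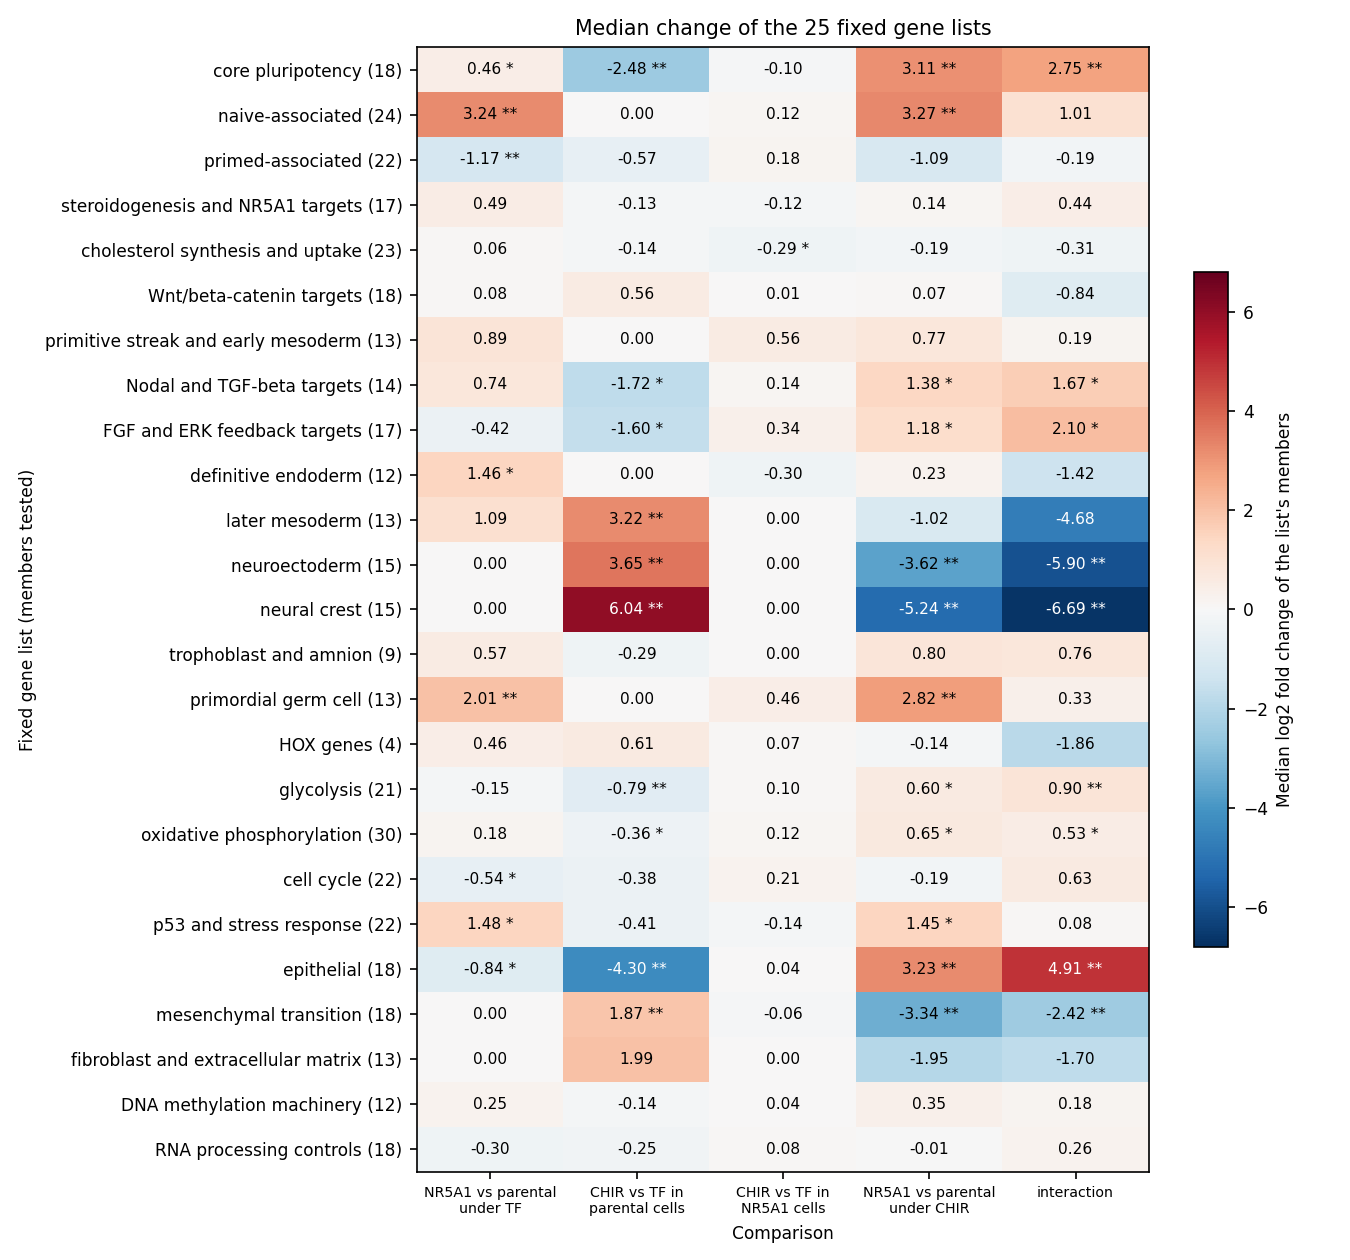
Median log2 fold change of the tested genes of each of the 25 lists (y axis) in the 5 comparisons (x axis), with dim genes at their lower bound except in the interaction; 1 star marks a camera adjusted p under 0.05 and 2 stars a call that also held with an estimated correlation. CHIR in NR5A1 cells has a single call, while the other comparisons have 8 to 12. Where the estimate was under the preset correlation, the second test was the less strict one.

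The interaction asked whether the change from TF to CHIR differs between NR5A1 and parental cells. It did for most core pluripotency and epithelial genes. Log2 interactions, positive where NR5A1 cells ended relatively higher, were 7.08 ± 0.08 for POU5F1, 6.96 ± 0.16 for NANOG, 1.03 ± 0.07 for SOX2 and 8.57 ± 0.18 for EPCAM, with 3 arrays per group. CDH1, below background in Parental_CHIR, had an interaction of at least 318-fold. Neural and neural crest genes went the other way, and PAX6, below background in Parental_TF and NR5A1_CHIR, had a negative interaction of at least 1022-fold. With the mean over its probes its measured log2 interaction was -8.75, against -13.39. TFAP2B and PAX3 also passed, but no size is given because their NR5A1 groups were both below background.

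Among genes above background on all 12 arrays, the largest positive interactions were those of ESRG (8.85 ± 0.25), EPCAM, the non-coding RNA LINC00698 (8.43 ± 0.26), the serine protease PRSS8 (8.00 ± 0.31) and the neuropeptide GAL (7.96 ± 0.13). The largest negative ones were those of WLS, a carrier needed for Wnt secretion (-7.92 ± 0.21), the matrix protein SPON1 (-7.72 ± 0.32), NRCAM (-7.71 ± 0.21), the Wnt receptor FZD10 (-7.65 ± 0.36) and the matrix linker HAPLN1 (-7.62 ± 0.19). LEFTY1, DPPA5 and TFCP2L1, below background in Parental_CHIR, had positive interactions of at least 71.7-fold, 41.57-fold and 6.39-fold. The LEFTY1 bound averages NR5A1_CHIR replicate 1, at 2.29, with replicates 2 and 3, at 4.93 and 4.79, and so depends on that array. The Wnt targets AXIN2 and SP5 had negative interactions, -2.78 ± 0.10 and, from a Parental_TF level below background, at least 65.3-fold. Their fellow member FZD7, a Wnt receptor, had a positive one of 3.57 ± 0.11, and the list did not pass (adjusted p = 0.184). KLF17 had -1.31 ± 0.13. KLF4 was below background in Parental_CHIR, so its interaction rests partly on background. TBXT was below background in both parental groups, so its values below are as measured and give no size of an interaction. KLF4 did not pass at 0.39 ± 0.23 (adjusted p = 0.152). KLF4 passed at -0.53 with normexp (adjusted p = 0.00134), at 0.69 in the value table (0.0495) and at 0.55 without Parental_TF replicate 1 (0.0382). TBXT did not pass at 2.34 ± 1.11 (adjusted p = 0.0843), and passed with quantile normalization (2.62, adjusted p = 0.0466), the value table (2.64, 0.0443), array weights (3.31, 0.00605), without Parental_TF replicate 3 (3.07, 0.0230) and without NR5A1_CHIR replicate 1 (3.18, 0.0124). On slide 2 alone it was -0.79.

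Of the 25 lists 9 had an interaction. Core pluripotency had 16 positive and 2 negative genes of 18, with 18 passing adjusted over the list alone (list adjusted p = 3.58e-33, and 2.72e-09 with an estimated correlation). Epithelial genes had 17 positive and 1 not passing of 18, with 18 passing adjusted over the list alone (list adjusted p = 1.40e-46, and 2.12e-33 with an estimated correlation). All 15 neuroectoderm genes (adjusted p = 3.83e-10, and 3.62e-11 with an estimated correlation) and all 15 neural crest genes tested (adjusted p = 3.40e-12, and 1.81e-06 with an estimated correlation) were negative, also when adjusted over each list alone, although several, such as PAX6 and TFAP2B, were below background in 2 or more groups. Of 18 mesenchymal transition genes 15 were negative, 2 positive and 1 did not pass, with 18 passing adjusted over the list alone (list adjusted p = 4.45e-06, and 8.94e-07 with an estimated correlation). Glycolysis had 16 positive, 2 negative and 3 not passing of 21, with 19 passing adjusted over the list alone (list adjusted p = 1.86e-05, and 0.0215 with an estimated correlation), and ALDOC had 3.46 ± 0.09. The other 3 calls were lost with an estimated correlation. FGF and ERK feedback targets had 15 positive, 1 negative and 1 not passing of 17, with 16 passing adjusted over the list alone (list adjusted p = 0.000242, and 0.145 with an estimated correlation). Nodal and TGF-beta targets had 9 positive, 3 negative and 2 not passing of 14, with 12 passing adjusted over the list alone (list adjusted p = 0.0147, 0.338 with an estimated correlation and 0.138 with normexp). Oxidative phosphorylation had 22 positive, 2 negative and 6 not passing of 30, with 25 passing adjusted over the list alone (list adjusted p = 0.0226, and 0.649 with an estimated correlation). That call was also lost with quantile normalization (0.188), the value table (0.215), slide as a block (0.0733), on slide 2 alone (0.0915) and without Parental_CHIR replicate 1 or 3 (0.0533 and 0.0512). Lists without a call that passed under alternatives were HOX genes (0.00981 with quantile normalization, 0.0120 in the value table), fibroblast and extracellular matrix (0.00422 and 0.00446), primordial germ cell (0.0313 and 0.0449), cell cycle (0.0172 with normexp) and later mesoderm (0.0454 with quantile normalization, 0.00854 with normexp, 0.00745 on slide 2 alone). With an array left out, later mesoderm passed without Parental_TF replicate 1 or 3 (0.0138 and 0.0323), NR5A1_TF replicate 1 (0.0242) or NR5A1_CHIR replicate 2 (0.0352), and cell cycle without NR5A1_CHIR replicate 1 (0.0163). Primordial germ cell genes passed without NR5A1_TF replicate 1 or 2 (0.0236 and 0.0317), and naive-associated genes without NR5A1_TF replicate 1 (0.0412).

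**Figure D3:**
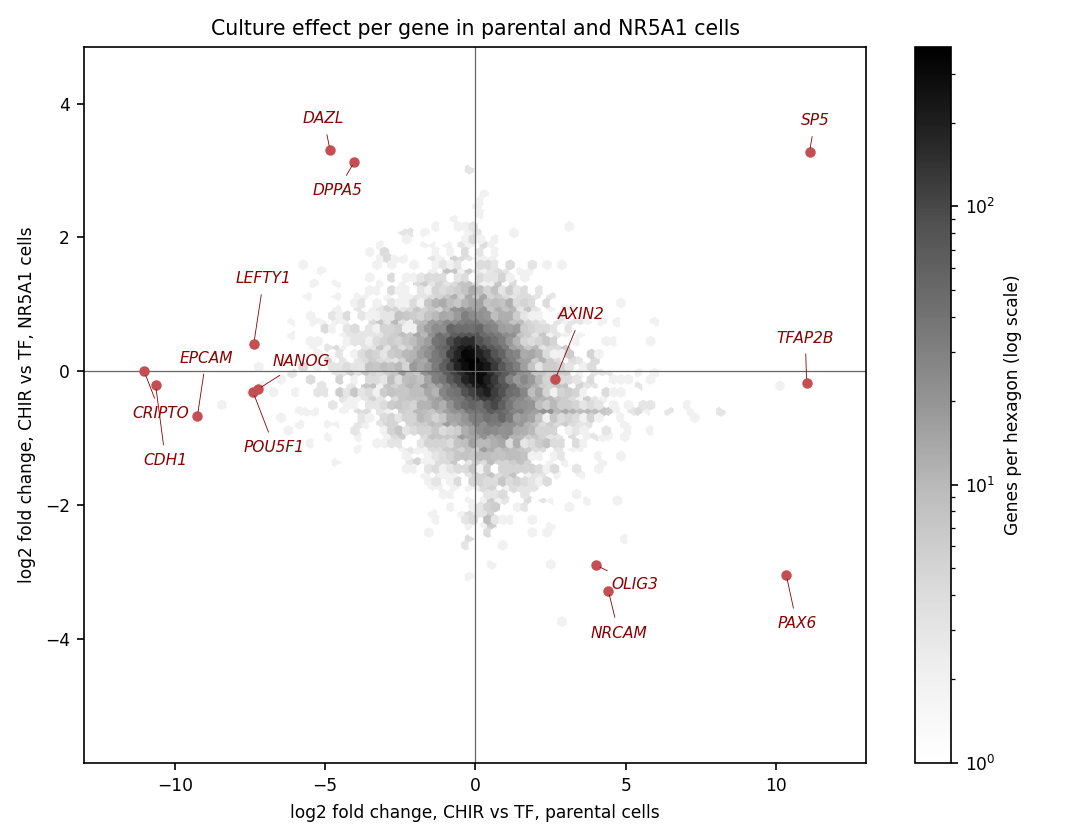
Log2 fold change from TF to CHIR in parental cells (x axis) against that in NR5A1 cells (y axis), each from 3 arrays per group, for all tested genes as hexagons shaded by count, with named genes as points, levels below background kept as measured, and no error bars. CRIPTO, CDH1, POU5F1, NANOG and TFAP2B change strongly in parental cells and lie near 0 in NR5A1 cells, while SP5, PAX6, DAZL and DPPA5 are far from 0 in both.

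An interaction was called for 14713 genes (67.7%), 7651 positive and 7062 negative; with slide as a block 13225 passed, and 12400 on slide 2 alone. Of the 14713, 6185 had changed with CHIR in parental cells only, 1745 in NR5A1 cells only, 2408 rose in parental and fell in NR5A1 cells, 2725 did the opposite, 527 rose and 651 fell in both, and 472 passed in neither. Across genes, the CHIR effects in parental and NR5A1 cells correlated at -0.195, from effects that share no array. Of 7381 genes passing in both, 30.5% moved the same way: 1124 rose and 1124 fell in both. The NR5A1 effects under TF and under CHIR correlated at 0.493, and 71.8% of 12058 genes passing in both moved the same way. Genes are not independent, so these shares carry no p-value. For lists that did not pass, median, mean and test differed in sign for 3 under TF (glycolysis, mesenchymal transition, fibroblast), 3 in parental cells (trophoblast, primordial germ cell, DNA methylation) and 5 in NR5A1 cells (later mesoderm, HOX, Nodal, fibroblast, DNA methylation). They differed for 2 lists under CHIR (Wnt, trophoblast) and 4 in the interaction (primed, primitive streak, trophoblast, DNA methylation).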

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

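For the patterns weighed here, the tests of the opposed CHIR effects and of the NR5A1 probe were chosen only after the result was seen, while those of NR5A1_CHIR replicate 1 were written down first, except the spread set beside the scaling test. A difference between groups put the following results here: the change from TF to CHIR differed between NR5A1 and parental cells by the interaction test in 14713 genes. The list medians of the log2 interaction were 2.75 for core pluripotency, 4.91 for epithelial genes, 2.10 for FGF and ERK feedback targets, 1.67 for Nodal and TGF-beta targets, 0.903 for glycolysis and 0.527 for oxidative phosphorylation. They were -5.90 for neuroectoderm, -6.69 for neural crest and -2.42 for mesenchymal transition. Single genes were ESRG at 8.85, EPCAM at 8.57, LINC00698 at 8.43, PRSS8 at 8.00, GAL at 7.96, LEFTY1 at 7.78, POU5F1 at 7.08, NANOG at 6.96, TFCP2L1 at 4.56 and SOX2 at 1.03. Negative ones were KLF17 at -1.31, SOX17 at -2.10, AXIN2 at -2.78, HAPLN1 at -7.62, FZD10 at -7.65, NRCAM at -7.71, SPON1 at -7.72 and WLS at -7.92. LEFTY1 and TFCP2L1 were below background in Parental_CHIR, so their interactions are given more safely as at least 71.7-fold and 6.39-fold. The LEFTY1 bound still depends on the low NR5A1_CHIR replicate 1 described below. The interaction of SOX17, below background in every group but NR5A1_TF, has no measured size. The list medians include such genes that were below background in some groups.

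The CHIR effects in parental and NR5A1 cells were opposed (correlation across genes -0.195). Quantile normalization did not remove this, since the correlation nearest to 0 with it or in the deposited value table was -0.136. The value table is quantile normalized too, so a single other kind of scaling was tried. It moved the correlation toward 0, and scaling as a part of the cause is not excluded. Slide was excluded, since slide 2 alone gave -0.160. Passage could have added to the parental effect: the labelled passage of the 2 parental groups differed by 13 in number, and no array separates it from culture, so this cannot be told. A biological effect of NR5A1 on the response to CHIR stays open, and no test separated it from passage.

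The NR5A1 probe was not well above background in cells that carry introduced NR5A1. The highest correlation between a Parental_TF and an NR5A1_TF array was 0.912, against at least 0.989 between replicates. This does not exclude that these arrays held parental cells of another culture, because replicates may differ only technically and the labelled passage differs too. The probe may lie outside the part of the gene that was introduced, or may not report the gene. It was above background on 0 NR5A1 arrays, and the data cannot tell these apart. The higher STAR (3.18 ± 0.11) and NR0B1 (3.70 ± 0.23) in NR5A1 cells do not measure NR5A1 itself.

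NR5A1_CHIR replicate 1 stood apart from replicates 2 and 3. LEFTY1 levels were 2.29, 4.93 and 4.79 in replicates 1, 2 and 3, those of NODAL were 2.74, 4.61 and 4.29, and those of TBXT -3.90, -1.14 and -1.62. The deviation of replicate 1 and that of Parental_TF replicate 3, also on slide 2, correlated across genes at -0.111, which argues against a signature of slide 2. Replicates 2 and 3 are the only arrays on slide 3, and no other group was on it. A signature of slide 3 therefore could not be tested and stays open, as does brightness-dependent scaling. After quantile normalization the SD of the deviation of replicate 1 was 0.436 against at most 0.408 in other groups. That margin of 0.0276 is less than the SD of 0.0571 over the arrays of those groups. Genes of the lists differed over 2-fold more often (14 of 352, 3.98%) than other genes (309 of 18810, 1.64%), with an odds ratio of 2.48 (Fisher's exact test across genes, p = 0.00273). Genes are not independent, and the Nodal targets LEFTY1, LEFTY2, NODAL and SMAD7 were among the 14, so the p-value is too small. Other replicates were not tested in this way, so list genes may differ more on any array. A different state of the culture may explain the replicate, but the odds ratio does not settle it. A signature of slide 3 is not separated from it, and scaling may have added to it.

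Splits of the arrays were compared with the real grouping. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05: the real groups gave 14655, 14831, 9711 and 17053 genes, and the highest other split gave 1, 1, 1 and 0, so the real split alone, 1 of 10, reached its count. For the interaction, the real grouping was 1 of 100 with 14713 genes. The highest other, 11740, kept the parental groups and exchanged all labels of NR5A1 arrays, and so still holds the real CHIR effect of parental cells.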

How the results depend on the processing

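Where a call or count changed, the cause was not tested unless stated. Counts of passing genes kept within 1.5 times under every alternative except the stricter thresholds, which select fewer genes by construction. At least 2-fold changes numbered 5823 for NR5A1 under TF, 6024 for CHIR in parental cells, 1848 for CHIR in NR5A1 cells, 8907 for NR5A1 under CHIR and 7730 for the interaction, and an adjusted p under 0.01 left 6323 for CHIR in NR5A1 cells. With 1 array left out, the counts ranged over 13621 to 15401, 13749 to 15538, 8170 to 10527, 16216 to 17165 and 13852 to 15205 in the same order, and the numbers of lists over 7 to 10, 8 to 12, 0 to 7, 12 to 13 and 8 to 12. For CHIR in NR5A1 cells, 0 lists passed without NR5A1_TF replicate 1 or NR5A1_CHIR replicate 3, 7 without NR5A1_CHIR replicate 1, and 8 with normexp. With an estimated correlation 3 of 8 lists were left under TF, 0 of 1 for CHIR in NR5A1 cells and 7 of 12 for NR5A1 under CHIR. The 3 left under TF had smaller adjusted p-values than with the preset correlation, so the test was less strict for them. The directional fry test called 22, 24, 18, 21 and 22 lists and the mixed one 25, 25, 24, 25 and 25, since fry does not compare a list with other genes. The correlation of the CHIR effects was -0.137 with quantile normalization, -0.239 with normexp, -0.136 in the value table, -0.131 without a filter and -0.160 with slide as a block or on slide 2 alone. That of the NR5A1 effects was 0.518, 0.464, 0.518 and 0.446 for the first 4 of these. In CHIR against TF in NR5A1 cells, LEFTY1 reversed to -1.30 with slide as a block (adjusted p = 0.00228) and on slide 2 alone (adjusted p = 0.0112), and POU5F1 to 0.0883 with quantile normalization and 0.0114 in the value table. The interaction of KLF4 reversed to -0.53 with normexp. With normexp the share of higher genes for CHIR in NR5A1 cells was 42.0%, against 53.4%. Of 14450 values of named genes under alternatives, 14285 kept direction and side of the threshold, 135 were weaker, 25 stronger and 5 reversed. With slide as a fixed block, 15 of 119 named genes no longer passed for CHIR against TF in NR5A1 cells, against at most 2 in any other comparison. That fit takes NR5A1_CHIR from replicate 1 alone. The changes were also smallest in this comparison, with an SD across genes of 0.644. Leaving out NR5A1_CHIR replicate 2 or 3 lost 7 named genes each. The loss can therefore not be assigned to slide. With normexp the folds of dim genes shrank, such as that of TFCP2L1 for CHIR in parental cells from -3.78 to -0.87. Of 2625 list values 2352 were the same, 55 weaker, 218 stronger and 0 reversed. Replicate numbers did not pair the samples: over 18 pairs with the same number, deviations correlated at -0.045 to 0.0921 and 0 exceeded 0.1. A block on them gave 14558, 14771, 9644, 16986 and 14603 genes, and under TF it lost the core pluripotency list (adjusted p = 0.0683), as it did oxidative phosphorylation for CHIR in parental cells (0.0604), and it added cell cycle (0.0455) and later mesoderm (0.0456) in the interaction. Signal over background limits folds: 52.6% to 58.8% of spots per array were well above background.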

Other observations

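The gene lists behind the next 2 paragraphs and the chromosome and mixture tests were chosen only after the result was seen, with germline, imprinted and brain predictions written down before their lists were tested. Most germline genes that could be tested rose from TF to CHIR in NR5A1 cells. TDRD6 and TDRD9, tudor proteins of germ cell granules, rose by 2.47 ± 0.20 and 2.45 ± 0.33 (n = 3 per group), and DMRTB1, a testis transcription factor, by 1.68 ± 0.23. Of 38 germline genes with a probe, 23 were bright enough to be tested. Of these 19 rose and 4 did not pass, with a median of 1.39. A gene above background only in NR5A1_CHIR, such as MAEL, could only be seen to rise. The filter can thus favour a rise of the list, also in the camera test. DMRTB1 was already at least 113-fold and TDRD1, another tudor protein, at least 34.5-fold higher in NR5A1 than in parental cells under TF. Without the 3 genes seen first, 16 of 20 rose and 4 did not pass, with a camera p of 1.46e-05, or 0.00191 with an estimated correlation.

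Parental cells under CHIR carried genes of the midbrain and its border. DMBX1, a midbrain homeobox factor, was at least 109-fold higher than under TF, MEIS2 at least 49.0-fold, PAX2, a factor of the midbrain-hindbrain border, at least 43.0-fold and EN1, another border factor, at least 7.54-fold. Of 17 midbrain genes tested 15 rose and 2 fell, with a median of 5.87. Of 12 forebrain genes 6 rose, 4 fell and 2 did not pass: DLX2 was at least 42.2-fold higher, while HESX1, a factor of the anterior forebrain, fell by 5.66 ± 0.16. Rises of 2-fold or more were found for 15 of 20 midbrain genes with a probe (75%), 6 of 20 forebrain genes (30%) and 5 of 20 hindbrain genes (25%). Genes too dim to be tested count there as not risen, and of the genes tested 15 of 17, 6 of 12 and 5 of 8 rose, so no contrast with the hindbrain is claimed. Over all genes with a probe there was a Fisher exact p of 0.0104 for midbrain against forebrain. Some of these genes had been seen first, and among those that had not, 9 of 13 and 4 of 15 rose (Fisher exact p = 0.0557), so a midbrain bias may be present but cannot be told.

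Imprinted genes were tested in NR5A1 against parental cells under TF. DLK1 rose by 5.76 ± 0.18, IGF2 by 4.97 ± 0.14 and CDKN1C by 2.35 ± 0.15, DIRAS3 was at least 61.4-fold higher, H19 at least 4.03-fold lower and NNAT fell by 2.46 ± 0.06. Of 28 genes 11 rose and 10 fell (camera p = 0.0464, and 0.129 with an estimated correlation), and the list also moved in parental cells under CHIR (camera p = 0.0486, and 0.133 with an estimated correlation) and, downward, in NR5A1 cells under CHIR (camera p = 0.0209, and 0.0787 with an estimated correlation), so loss of an imprint cannot be told from these data.

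That parental cells were mixed into the NR5A1 cultures was tested because primed genes stayed above background there. The 17 primed-associated genes that fell had a median of -2.50, which is 17.6% of the parental level. Of 781 genes above background in parental cells only, 47 had bounds beyond that, and CUZD1 stood at 0.314% or less. This excludes a mixture with cells like those of Parental_TF as the source of the median level. Parental cells of another culture may express these genes less, so a mixture with such cells was not tested. Gain or loss of a whole chromosome was tested on 22 autosomes, and the largest shift of 1 sign in both cultures, taken as the smaller of the 2, was 0.104, on chromosome 21. Chromosome 19 stood at 0.0929 under TF and 0.241 under CHIR, and chromosome 13 at 0.0445 and -0.215. None came near the shift of a whole copy in every cell, while a copy in part of the cells was not tested.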
